A study of Mus musculus with 12 samples.

How the data were processed

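RNA-seq was done on Ebf1-deficient mouse fetal liver progenitors that carried a retrovirus for wild-type EBF1 or EBF1 E271A, in 12 libraries that form 4 groups of 3. One population was sorted as GFP-positive CD19-negative cells at day 7 of culture on OP9-DL1 stroma, and the other as GFP-positive cells at day 3. Per the labels' protocols, the day 7 libraries were made with a SMART-seq v4 kit and the day 3 libraries with a NEBNext low input kit. The series' design text speaks of independent experiments for each population, so p-values of single genes measure the spread between experiments. Time, gate, kit and count table all differ between the populations. Day 7 was therefore not tested against day 3, and only the difference of the E271A effects was.

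The deposited counts are whole-number reads per gene, one column per library, with no replicates pooled. Per the submitters' processing notes, the tools included STAR 2.7.4a, SAMtools 1.10, featureCounts, Subread 2.0.0, deepTools 3.3.2 and DESeq2, and the builds were mm10 and GRCm38.p6. Aligner settings, the strand setting of the counting and the annotation version are not given in the sources used here. Reads shared by near-identical genes, such as the globin pairs Hba-a1 and Hba-a2 or the Dcpp family, cannot be assigned with certainty, and neither can reads of overlapping or antisense genes. The deposited normalized signal of each library equals its counts times 1 factor per library. Those factors equal the inverse of DESeq2 size factors within a relative difference of 0.00011. The day 7 normalized table held genes with a total of at least 10 counts. These signal values were used only to check the factors and to restore symbols.

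The deposited counts covered 55224 genes at day 7 and 24368 at day 3, of which 53543 and 23228 had a symbol found in GENCODE M21 (GRCm38), the source of the coordinates. At day 3, 27 symbols stood as spreadsheet dates and were restored through the normalized table, and 22 date symbols at day 7 were left as they were. Mitochondrially encoded genes were at 0 in every day 7 library and had no rows at day 3, so that list was not tested. Ighm, Trbc1, Trbc2 and Tcrg-C1 had no rows at day 3. The adult globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt held 0 or 1 count per library at day 3. No count table had a row without a gene name. Replicates were compared pairwise by a chi-square of their counts. The lowest value per degree of freedom was 14.8, so that no pair was a copy of 1 library.

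Each population was tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr (minimum count 10), scaled by TMM and tested with the quasi-likelihood F test (glmQLFit with robust=TRUE, two-sided). P-values were adjusted by Benjamini-Hochberg and called at 0.05, for E271A minus wild type. CPM values are TMM-scaled unless raw CPM is named, and errors after ± are SD over 3 libraries. The difference between the E271A effects was tested as an interaction over all 12 libraries, on the 23108 genes shared by the tables before filtering. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were alternatives. An adjusted p that DESeq2 gave as NA stayed NA.

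Before the data were examined, 17 gene lists with 301 genes were fixed for lineages, pathways and other cell types that the gate could hold. They are early B lineage, Notch targets, T lineage, shared lymphoid, NK and innate lymphoid, myeloid, dendritic, stem and multipotent progenitor, erythroid with megakaryocyte and mast, stromal feeder, cell cycle, p53 and apoptosis, immediate early and heat shock, interferon response, interleukin 7 and STAT5 response, nuclear import receptors and mitochondrially encoded genes. Each list with at least 3 tested members was tested by limma's camera with a preset inter-gene correlation of 0.01, adjusted over 16 lists per comparison. At this preset the genes of a list count as nearly independent, so the camera p-value does not measure the spread between experiments. An estimated correlation and fry stood beside camera. A list score is the mean log2 CPM of the tested members with a prior count of 2, compared between groups by a two-sided exact permutation test, whose smallest p for 3 against 3 is 0.1.

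The rule for named genes was also fixed beforehand. It took Ebf1, Tnpo3, Cd19, Pax5, Gata3, Tcf7 and Notch1 whatever their result, then the 5 largest called changes in each direction (a mean of at least 5 CPM in the higher group, no overlap between the groups, and no Gm number, Rik clone or pseudogene), then up to 3 called members of each list, or 4 for the B, T and Notch lists. For the interaction it took the 4 largest differences in each direction among called genes. Because edgeR called 0 genes, these parts of the rule were applied to the DESeq2 calls, a choice made after seeing the data. Other list members were named to describe their list, and were chosen after their values were seen, as were Lars2, Il2ra and the genes shared by both comparisons.

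The scripts were tested on simulated counts drawn from the real means, dispersions and library sizes. Genes given a change were drawn from those with a mean of at least 5 CPM. Noise was drawn for each gene apart, so a structure of the samples shared by many genes was not simulated. The rates below hold for such genes and noise only. Among 15135 simulated genes of the day 7 comparison, edgeR called 81% of genes changed by a log2 of 1 and 98% of those changed by 2. It called 85% and 96% among 12948 genes of the day 3 comparison. Beside the changed genes, edgeR also called 15 unchanged genes at day 7 and 21 at day 3, and DESeq2 called 65 and 49. With no gene changed, edgeR called 0 genes in both, and DESeq2 called 8 and 12. DESeq2 thus called more unchanged genes than edgeR in both comparisons. In the simulated interaction over 11809 genes, edgeR called 90.5% of genes changed by a log2 of 2.

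The alternatives were RLE scaling, no filter, a filter of 1 CPM in 3 libraries, robust=FALSE, a log2 threshold of 1, DESeq2, limma-voom, all 12 libraries in 1 fit, the replicate number as a block, and each library left out in turn. DESeq2 with the block, DESeq2 with libraries left out, both replicate 3 libraries left out at day 7, both replicate 1 libraries left out at day 3, and the overlap of genes at an unadjusted p under 0.05 were added after seeing the data.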

Results

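Gene expression was measured by RNA-seq in mouse progenitors that lack Ebf1, the transcription factor that commits lymphoid progenitors to the B lineage. c-kit-positive progenitors from Ebf1-deficient fetal liver received a retrovirus that encoded GFP together with either wild-type EBF1 or EBF1 with the E271A amino acid exchange. The cells were grown on OP9-DL1, a stromal line that presents the Notch ligand Delta-like 1 and so favours T lineage development. The E271A exchange is studied for its effect on the contact of EBF1 with the nuclear import receptor TNPO3. The comparison asks which genes E271A leaves at another level than wild-type EBF1. Cells were taken as GFP-positive CD19-negative cells at day 7, a gate that removes cells with CD19 protein, and as all GFP-positive cells at day 3. Each of the 4 groups had 3 libraries. Library totals ranged from 27146054 to 42507460 counts at day 7 and from 25839575 to 36368140 at day 3.

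Ebf1 itself (chromosome 11, 44617317 to 45008091, GRCm38) was counted in every library. At day 7 it stood at 551, 577 and 436 CPM in the wild-type libraries and at 470, 445 and 489 CPM in the E271A libraries. The log2 difference was -0.16, with a 95% interval from -0.41 to 0.10. At day 3 it stood at 408, 358 and 393 CPM with wild type and at 504, 376 and 384 CPM with E271A. The log2 difference was 0.12, with an interval from -0.15 to 0.40. It was -0.023 without E271A replicate 1. Both intervals include 0, and counts per gene cannot tell the mutant from wild type or the vector from transcripts of the targeted locus. Tnpo3 (chromosome 6, 29540827 to 29609887), which encodes TNPO3, was at 209 ± 8.46 CPM with wild type and 208 ± 11.3 CPM with E271A at day 7, and at 210 ± 6.00 and 201 ± 13.0 CPM at day 3.

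In the CD19-negative cells at day 7, genes of the T lineage were higher with E271A than with wild-type EBF1. Of 19 T lineage genes tested, 18 were higher and 1, Cd4, was lower, with a mean log2 difference of 2.02 and a median of 2.47 (camera, adjusted p = 4.97e-12). The call was lost with an estimated correlation (adjusted p = 0.678) and in fry (adjusted p = 0.77). Cd28, a costimulatory receptor of T cells (chromosome 1, 60716800 to 60773359), was at 1.36 ± 0.231 CPM with wild type and 5.48 ± 2.74 CPM with E271A, a log2 difference of 2 (SE 0.425). Cd7, an early surface marker of T and NK progenitors (chromosome 11, 121036747 to 121039418), was at 5.84 ± 2.15 and 16.1 ± 5.86 CPM. Lat, an adaptor of T cell receptor signalling (chromosome 7, 126363824 to 126369570), was at 24.9 ± 4.01 and 43.4 ± 8.64 CPM. In these 3 genes every E271A library lay above every wild-type library. DESeq2 called them at adjusted p = 0.00297, 0.0104 and 0.0193. With edgeR they were the 3 of 19 genes called when adjusted over the list alone, and over all 15135 genes edgeR called 0. Larger but more variable differences that neither edgeR nor DESeq2 called over all genes included Tcrg-C1, a T cell receptor gamma constant gene (6.51 ± 9.52 against 71.1 ± 108 CPM), and Tcf7, which encodes the T lineage factor TCF1 (10.2 ± 8.33 against 56.6 ± 74.5 CPM). The same held for Cd247 (1.35 ± 1.42 against 9.34 ± 9.47 CPM), Itk (1.13 ± 0.778 against 6.74 ± 6.80 CPM) and Gata3 (1.19 ± 1.11 against 5.89 ± 8.14 CPM). These differences were smaller without E271A replicate 3. Without it the log2 difference was 0.4 for Tcrg-C1, 0.431 for Tcf7, 1.537 for Cd247, 1.407 for Itk and 0.039 for Gata3, against 3.44, 2.47, 2.78, 2.57 and 2.30 with all libraries. Trbc2 and Cd3d had log2 differences of 2.82 and 2.79, which became -0.669 and -0.295 without it. These fits kept wild-type replicate 3, the wild-type library with the highest T lineage score. With another single library left out, the log2 difference reached at most 6.122 for Tcrg-C1, 3.35 for Tcf7, 4.089 for Cd247 and 3.245 for Itk. It reached at most 3.39 for Gata3, 5.583 for Trbc2 and 6.452 for Cd3d.

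The T lineage score, in mean log2 CPM, was -0.22, -0.14 and 2.50 in the wild-type libraries and 0.74, 2.35 and 4.59 in the E271A libraries. The groups overlapped, and the difference of 1.84 had an exact permutation p of 0.3 (two-sided, smallest possible 0.1). This test ignored the replicate number, so a shift of replicate 3 common to both groups counted as spread. For each replicate number the E271A score lay above the wild-type score, although the labels do not say that the numbers pair the samples. In both groups replicate 3 had the highest score for the T lineage, early B lineage, Notch target and shared lymphoid lists. That did not hold for every list, for example not for the myeloid list. Replicate 3 also stood apart in both groups in 2 genes chosen after their values were seen. Lars2, a mitochondrial leucyl-tRNA synthetase gene, was at 5850 and 5800 raw CPM in its wild-type and E271A libraries and between 378 and 477 raw CPM in the other 4. Il2ra, a marker of early T cell progenitors and a Notch target, held 755 and 3971 counts in these libraries and at most 4 in the others. The T score was higher with E271A by 1.72 without both replicate 3 libraries and by 2.08 between those 2 libraries.

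**Figure D1:**
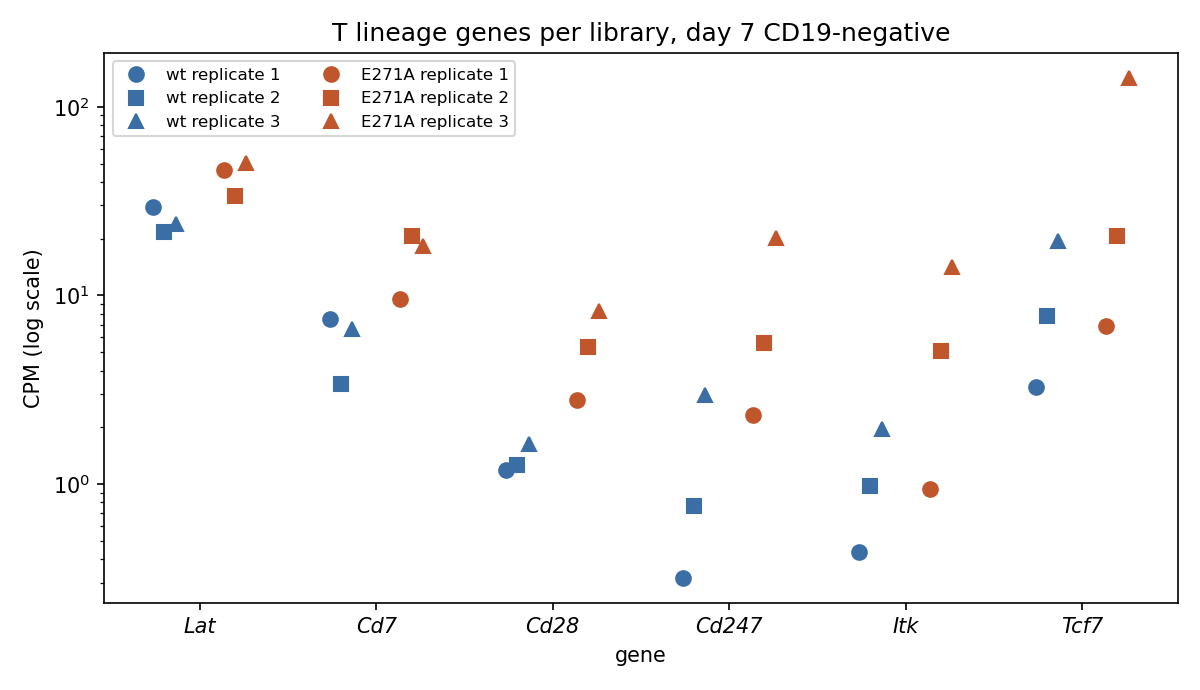
CPM (log scale) of 6 T lineage genes in each day 7 library, with blue for wild type, orange for E271A and the marker shape for the replicate. Every E271A library lies above every wild-type library for Lat, Cd7 and Cd28, while Cd247, Itk and Tcf7 overlap between the groups and are highest in E271A replicate 3.

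The NK and innate lymphoid list also rose at day 7, with 17 of 18 members higher, Rora lower and a mean log2 difference of 0.89 (camera, adjusted p = 0.000128). The call was lost with an estimated correlation (adjusted p = 0.678) and in fry (0.77). The list scores overlapped between the groups (exact permutation p = 0.3). The receptor genes Klrd1 (0.915 ± 0.478 against 3.68 ± 2.58 CPM) and Klrk1 (0.837 ± 0.516 against 2.55 ± 0.797 CPM) were among them. EdgeR and DESeq2 called 0 members. Ccr9, a chemokine receptor gene of thymus-seeding progenitors that was fixed in the dendritic list (chromosome 9, 123678439 to 123784330), was at 0.388 ± 0.312 CPM with wild type and 10.2 ± 7.47 CPM with E271A. The log2 difference was 4.70 (SE 0.987, DESeq2 adjusted p = 0.029, edgeR adjusted p = 0.728). Among genes with at least 5 CPM in the higher group and no overlap of the groups, the largest DESeq2 increases also included Adgrg5 (2.03 ± 0.618 against 8.40 ± 6.15 CPM), Ctsw, a protease gene of cytotoxic lymphocytes (2.23 ± 1.28 against 8.07 ± 3.69 CPM), and the galectin gene Lgals3 (5.94 ± 0.888 against 20.5 ± 12.8 CPM).

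The erythroid, megakaryocyte and mast list fell at day 7, with 10 of 16 members lower and a mean log2 difference of -0.23 (camera, adjusted p = 0.00355). With an estimated correlation the adjusted p was 0.678, and in fry 0.77. The list scores overlapped between the groups (exact permutation p = 0.4). Its lower members included the globins and a red cell surface gene. Hba-a1 was at 1180 ± 536 CPM with wild type and 574 ± 31.0 CPM with E271A (DESeq2 adjusted p = 0.0225), Hbb-bs at 2350 ± 1020 and 1270 ± 155 CPM, and Gypa at 140 ± 51.5 and 83.1 ± 5.24 CPM. The groups overlapped in Hba-a1, with wild-type replicate 2 at 594 CPM and E271A replicate 2 at 607 CPM. The erythroid factor genes Gata1 (log2 difference 0.20) and Klf1 (-0.09) were not called. Outside the list, Alas2, the erythroid enzyme of heme synthesis (chromosome X, 150547375 to 150570638), was at 192 ± 93.4 CPM with wild type and 59.7 ± 9.47 CPM with E271A (DESeq2 adjusted p = 0.0211). The list lost its call without both replicate 3 libraries (adjusted p = 0.132), without wild-type replicate 1 (0.196) and without E271A replicate 3 (0.154).

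The p53 and apoptosis list also fell, with 10 of 13 members lower and a mean of -0.16 (camera, adjusted p = 0.00355). This call was lost with an estimated correlation (adjusted p = 0.678), in fry (0.77) and without wild-type replicate 1 (0.11). The list scores were 5.11 ± 0.12 with wild type and 4.95 ± 0.06 with E271A, without overlap (exact permutation p = 0.1, the smallest possible). Phlda3, a p53 target, was at 130 ± 18.8 CPM with wild type and 81.2 ± 13.8 CPM with E271A (DESeq2 adjusted p = 0.0151). Cd34, a surface marker of stem and progenitor cells (chromosome 1, 194938819 to 194961279), was at 730 ± 57.1 and 500 ± 73.7 CPM (DESeq2 adjusted p = 0.0193), while its list was not called (camera, adjusted p = 0.27). Among annotated genes with at least 5 CPM in the higher group and no overlap of the groups, the largest DESeq2 decreases were in Dcpp2 (9.54 ± 5.56 against 2.31 ± 1.11 CPM), Fcer2a, the low-affinity IgE receptor of B cells (15.9 ± 6.81 against 4.72 ± 0.636 CPM), and Alas2. They were followed by Igfbp3 (8.45 ± 1.68 against 2.69 ± 0.115 CPM) and Myo5b (15.2 ± 4.79 against 4.90 ± 2.01 CPM).

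At day 7 the early B lineage list had 8 members higher and 16 lower (mean log2 difference -0.15; camera, adjusted p = 0.0815, 0.683 with an estimated correlation and 0.77 in fry). By camera at the preset correlation it passed the threshold without wild-type replicate 1 (adjusted p = 5.16e-07) and without E271A replicate 3 (0.00095), and turned upward without wild-type replicate 3 (0.465). Igll1, which encodes a surrogate light chain, was at 918 ± 114 and 919 ± 119 CPM, and Vpreb1, its partner, at 59.4 ± 16.7 and 34.3 ± 7.89 CPM. Cd19 was at 6.70 ± 3.28 and 7.97 ± 2.53 CPM in cells sorted for low CD19 protein, and Pax5 at 3.44 ± 2.54 and 2.45 ± 2.03 CPM. The Notch targets had 8 members higher and 4 lower (mean 0.38; camera, adjusted p = 0.288). Ptcra, the pre-T cell receptor alpha gene, was at 0.942 ± 1.63 and 6.78 ± 8.35 CPM, and Hes1 at 22.0 ± 1.94 and 27.6 ± 0.966 CPM. Heyl was at 25.9 ± 7.72 and 17.0 ± 0.601 CPM, and Notch1 at 12.5 ± 8.48 and 22.6 ± 18.5 CPM. The Notch list passed the threshold without wild-type replicate 3 (adjusted p = 0.00852), without E271A replicate 1 (0.0338) and without both replicate 3 libraries (0.0495), and turned downward without E271A replicate 3 (0.95). Camera did not call the interferon response, cell cycle and nuclear import receptor lists (adjusted p = 0.0815 each). Nor did it call the shared lymphoid (0.26), myeloid (0.265), dendritic (0.697), stromal feeder (0.322), immediate early and heat shock (0.961) and interleukin 7 and STAT5 response lists (0.225). The camera direction was down for the immediate early list, whose median and mean were both 0.05, and down for the interleukin 7 list, whose median was -0.11 and mean 0.07.

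Over all 15135 genes tested at day 7, edgeR called 0 genes (smallest adjusted p = 0.499), with 695 genes at an unadjusted p under 0.05 where chance gives 757. DESeq2 called 79 genes, 16 higher and 63 lower with E271A, and limma-voom called 0. The DESeq2 count was 37 without wild-type replicate 1, 120 without E271A replicate 1 and 50 without both replicate 3 libraries. The 3 libraries of one group lay wholly above or below the other in 9.38% of genes, where chance gives 10%.

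At day 3 the early B lineage genes were lower with E271A. Of 23 genes tested, 22 were lower and 1, Bank1, was higher, with a mean log2 difference of -0.39 and a median of -0.34 (camera, adjusted p = 2.04e-12). The call was lost with an estimated correlation (adjusted p = 0.304) and in fry (adjusted p = 0.283). The surrogate light chain genes Igll1 (chromosome 16, 16860671 to 16863985) and Vpreb1 (chromosome 16, 16868403 to 16870843) were at 606 ± 59.9 and 196 ± 24.0 CPM with wild type and at 452 ± 49.1 and 140 ± 18.2 CPM with E271A. Pou2af1, a B cell coactivator (chromosome 9, 51213708 to 51240080), was at 6.73 ± 2.65 and 2 ± 0.895 CPM, a log2 difference of -1.76 (SE 0.412). DESeq2 called these 3 genes at adjusted p = 0.0364, 0.0413 and 0.0151. Cd79b, a chain of the B cell receptor complex (116 ± 12.1 against 93.4 ± 6.70 CPM), and Vpreb3 (7.37 ± 1.94 against 3.78 ± 0.653 CPM) were also separated between the groups. With edgeR these 5 of the 23 genes were called when adjusted over the list alone, and over all 12948 genes edgeR called 0. Cd19 was at 38.5 ± 7.54 and 25.4 ± 9.21 CPM, and Pax5 at 16.1 ± 0.899 and 13.5 ± 5.59 CPM, neither called. The B score was 4.53, 4.36 and 4.59 in the wild-type libraries and 4.36, 3.85 and 4.08 in the E271A libraries (difference -0.40, exact permutation p = 0.1, the smallest possible). Lef1, a factor shared by early B and T cells (chromosome 3, 131110471 to 131224356), was at 37.7 ± 5.98 and 19.1 ± 6.79 CPM (DESeq2 adjusted p = 0.00832), while the shared lymphoid list was not called (camera, adjusted p = 0.136).

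Interferon response genes were higher with E271A at day 3, with 17 of 18 members higher, Ifit2 lower and a mean log2 difference of 0.41 (camera, adjusted p = 9.73e-13). The call was lost with an estimated correlation (adjusted p = 0.304) and in fry (0.283). Zbp1, a sensor of nucleic acids (chromosome 2, 173206612 to 173218923), was at 5.60 ± 1.61 and 11.4 ± 1.78 CPM and was the 1 member called by DESeq2 (adjusted p = 0.0492) and by edgeR over the list alone. Usp18 was at 131 ± 20 and 197 ± 36.3 CPM, Oasl2 at 84.5 ± 15.6 and 126 ± 21.9 CPM, and Irf7 at 196 ± 23.7 and 282 ± 55.8 CPM. The interferon score was 5.32, 5.44 and 5.07 in the wild-type libraries and 5.41, 5.79 and 5.83 in the E271A libraries (difference 0.40, exact permutation p = 0.2). E271A replicate 1 lay below wild-type replicate 2.

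**Figure D2:**
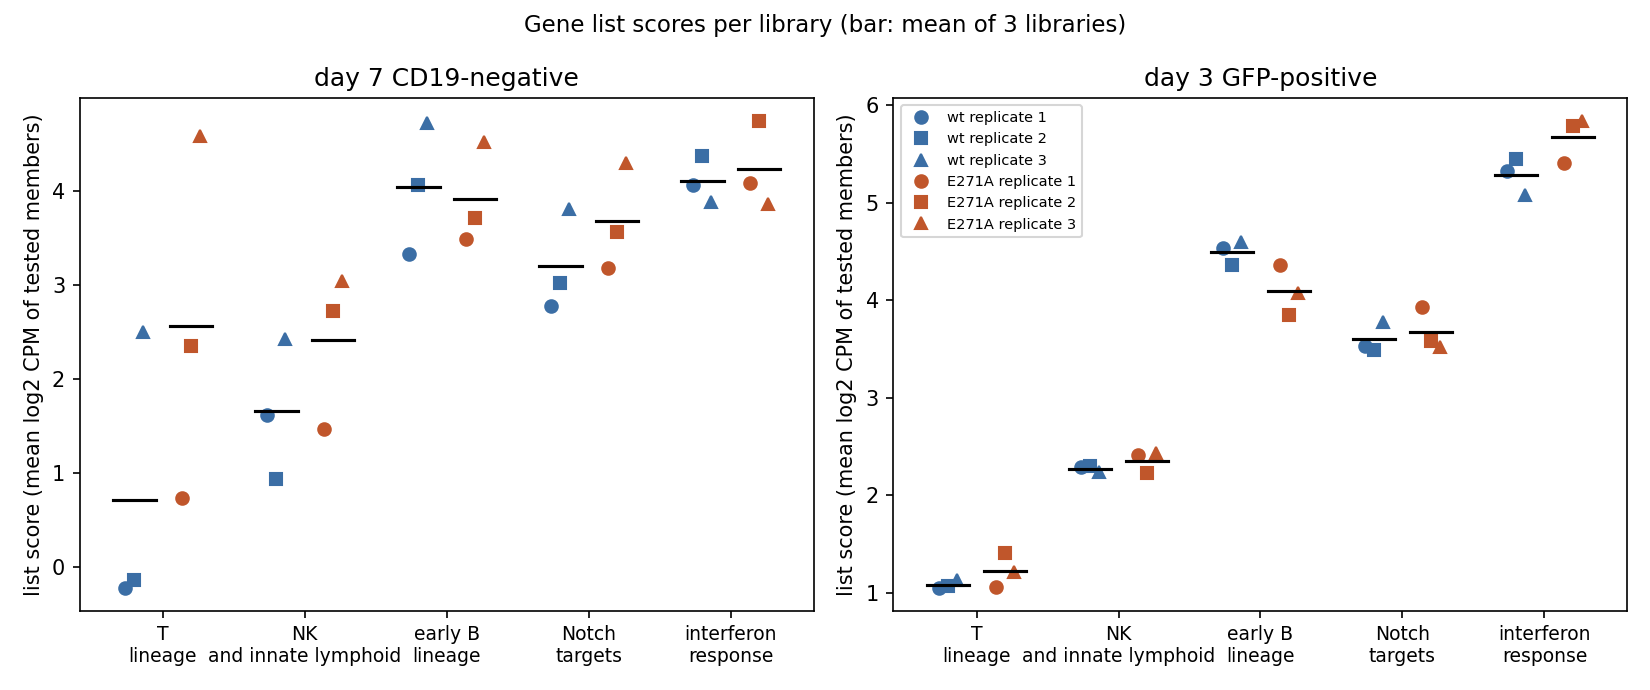
List scores, the mean log2 CPM of the tested members, for 5 gene lists in each library at day 7 (left) and day 3 (right, with its own axis range), with blue for wild type, orange for E271A, the marker shape for the replicate and a bar for the mean of 3 libraries. At day 7 the T lineage scores run from -0.22 to 2.50 with wild type and from 0.74 to 4.59 with E271A, and at day 3 the early B scores of E271A lie at or below those of wild type.

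The myeloid list rose at day 3 with 15 of 20 members higher and a mean log2 difference of 0.21 (camera, adjusted p = 0.00022). The call was lost with an estimated correlation (adjusted p = 0.427), in fry (0.381) and without wild-type replicate 2 (0.143). The neutrophil and monocyte genes S100a9 (118 ± 31.1 against 168 ± 10.9 CPM), Lyz2 (174 ± 57.5 against 251 ± 5.90 CPM) and Ly6c2 (3.85 ± 1.08 against 7.11 ± 0.354 CPM) were higher in every E271A library than in every wild-type library. In all, 6 members were separated upward and 1, Mafb (log2 difference -0.972), downward. The list scores overlapped between the groups (exact permutation p = 0.2). EdgeR and DESeq2 called 0 members. Among genes with at least 5 CPM in the higher group and no overlap of the groups, the largest DESeq2 increases included Chil3, a product of myeloid cells (4.27 ± 1.44 against 11.2 ± 0.493 CPM), and the neutrophil granule gene Ngp (57.9 ± 21.3 against 117 ± 5.32 CPM). They also included Gzma, which encodes granzyme A (38.4 ± 3.42 against 64.1 ± 6.91 CPM), and Tgm2 (11 ± 1.46 against 18.4 ± 1.12 CPM). In the same set of genes the largest decreases were in Pou2af1, Bpifb3 (5.48 ± 0.447 against 1.91 ± 0.754 CPM), Fcer2a (14.8 ± 2.63 against 5.93 ± 1.16 CPM), Matn1 (14.6 ± 4.09 against 6.23 ± 1.06 CPM) and Sardh (17.8 ± 2.19 against 8.32 ± 1.39 CPM).

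The erythroid, megakaryocyte and mast list was called upward at day 3 with 11 of 11 tested members higher and a mean of 0.23 (camera, adjusted p = 0.0276). The call was lost with an estimated correlation (adjusted p = 0.304), in fry (0.107) and without the filter (0.196). The adult globins were not among these members, since they were listed at 0 or 1 count. The call was also lost in 5 of the 6 fits that left out 1 library, namely wild-type replicates 2 (0.113) and 3 (0.689) and E271A replicates 1 (0.102), 2 (0.186) and 3 (0.181). The list scores were 6.43 ± 0.04 with wild type and 6.67 ± 0.03 with E271A, without overlap (exact permutation p = 0.1, the smallest possible). T lineage and Notch target genes were not called at day 3. The T list had 10 of 15 members higher (mean 0.09; camera, adjusted p = 0.674). Gata3 stood at 6.32 ± 0.348 and 6.32 ± 0.564 CPM and Tcf7 at 3.19 ± 1.12 and 2.73 ± 0.643 CPM. The Notch list had 5 members higher and 8 lower (mean 0.04, median -0.04, camera downward with adjusted p = 0.531). Notch1 stood at 28.0 ± 0.283 and 27.3 ± 5.73 CPM and Hes1 at 54.6 ± 21.9 and 66.0 ± 2.84 CPM. Camera did not call the NK and innate lymphoid (adjusted p = 0.0875), cell cycle (0.0569), stem and multipotent progenitor (0.195) and nuclear import receptor lists (0.189). It did not call the p53 and apoptosis (0.261), interleukin 7 and STAT5 response (0.261), immediate early and heat shock (0.419), dendritic (0.441) and stromal feeder lists (0.685). For the dendritic and the immediate early list, camera pointed down while the median was 0.04 and 0.02 and the mean -0.05 and -0.06.

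Of 12948 genes tested at day 3, edgeR called 0 (smallest adjusted p = 0.186), with 522 at an unadjusted p under 0.05 where chance gives 647. DESeq2 called 32 genes, 9 higher and 23 lower, and limma-voom called 0. The edgeR count was 4 without wild-type replicate 1, 1 without E271A replicate 1 and 16 without both replicate 1 libraries. The DESeq2 count was 15 without E271A replicate 3, 66 without E271A replicate 1 and 51 without both replicate 1 libraries. The groups were fully separated in 9.85% of genes, where chance gives 10%.

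Whether the E271A effect was shared or differed between the populations was tested directly. Fold changes of the 11809 genes tested in both correlated with a Pearson r of 0.123 and a Spearman rho of 0.0823, across genes, which are not independent replicates. The Pearson r was 0.0443 without E271A replicate 2 of day 7. Among the 8887 genes with a wild-type mean of at least 5 CPM in both populations it was 0.169. With DESeq2 fold changes it was 0.046, but over all genes with a count in both populations, without the filter. That value therefore does not compare the tools on the same genes. At an unadjusted p under 0.05 in both, a threshold chosen after seeing that edgeR called no gene, 44 genes were lower with E271A in both. Independent lists give 6.8 (one-sided Fisher's exact test, p = 8.02e-24, which treats genes as independent). Combinations of splits of the libraries were counted for lower and higher genes together, by the larger of the same-way and opposite-way counts. Of 100 combinations, the real one included, 15 reached the real count of 53, so chance is not excluded. In turn 9 genes were higher in both, where independent lists give 4.6 (one-sided Fisher's exact test, p = 0.0429). This count was 4 without E271A replicate 2, 15 without wild-type replicate 3, 17 without E271A replicate 3 and 30 without E271A replicate 1 of day 7, and 14 without wild-type replicate 1 of day 3. Without E271A replicate 2 of day 3 the shared lower genes numbered 27. Among the shared lower genes were Fcer2a, Bpifb3 and the B lineage genes Cd79b and Vpreb1. They also included Chga, which encodes chromogranin A (261 ± 139 against 116 ± 3.32 CPM at day 7 and 79.4 ± 3.28 against 46.5 ± 4.42 CPM at day 3), and Rbp2 (15.3 ± 3.90 against 5.45 ± 0.749 CPM and 30.2 ± 4.02 against 21 ± 3.70 CPM). DESeq2 called 4 genes lower in both, Bpifb3, Hspb8, Dlg2 and Fcer2a, where independent lists give 0.1, and 0 higher in both. By the same count of genes called in both, 1 of the 100 combinations of splits, the real one, reached 4, and the highest other reached 3. The interaction test, the direct test of a difference, called 0 of 13071 genes with edgeR (464 at an unadjusted p under 0.05 where chance gives 654, smallest adjusted p = 0.421), 0 with limma-voom and 7 with DESeq2. The edgeR count was 3 without wild-type replicate 2 of day 7. DESeq2 gave a more positive E271A effect at day 7 for Ccr9, Cacna1c and Sardh and a more negative one for Itga2, Fndc5, Shisa2 and Psca. For wild type and E271A in turn, Sardh was at 182 and 233 CPM at day 7 and at 17.8 and 8.32 CPM at day 3. Psca was at 81.9 and 37.4 CPM at day 7 and at 284 and 285 CPM at day 3. By camera the T lineage list had a more positive effect at day 7 (adjusted p = 5.92e-11, median difference 2.21), a call lost with an estimated correlation (0.403) and in fry (0.578). The early B (0.0995), interferon response (0.127) and Notch target lists (0.62) did not differ past the threshold.

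**Figure D3:**
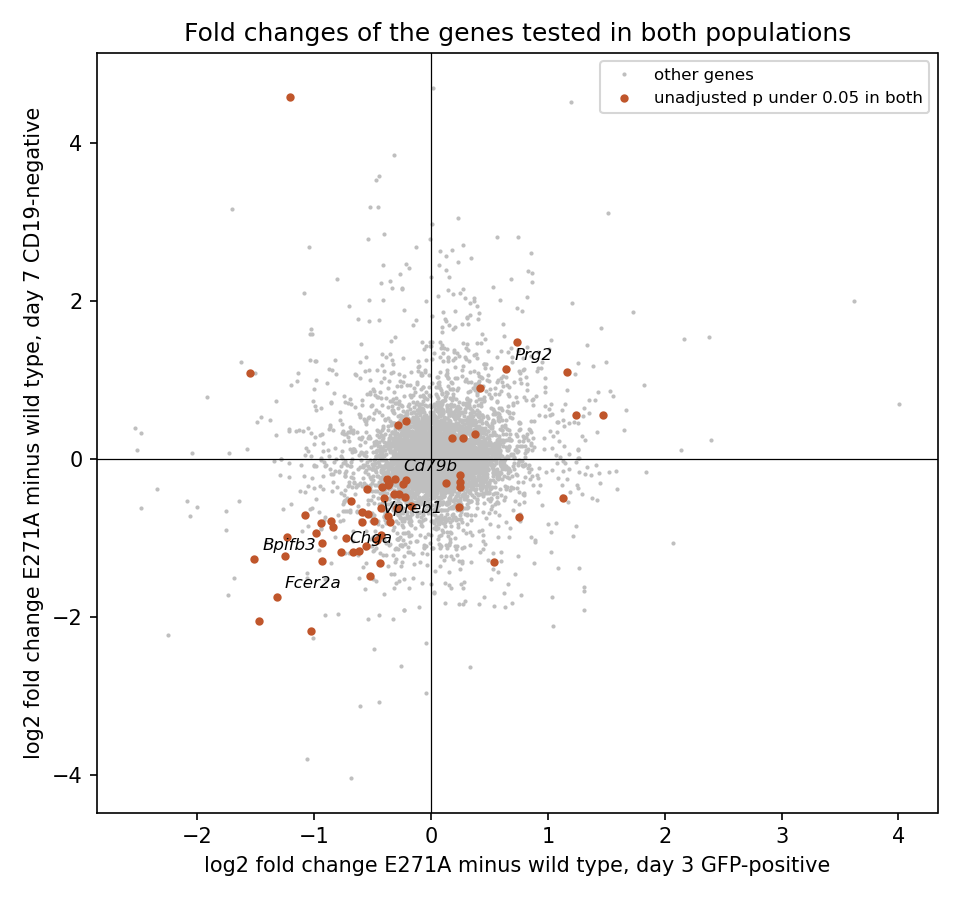
Log2 fold change of E271A against wild type at day 3 (x axis) and at day 7 (y axis) for the 11809 genes tested in both populations, with each point a gene. Orange points mark the 65 genes at an unadjusted p under 0.05 in both, of which 44 lie in the lower left and 9 in the upper right.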

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

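The tests of the replicate 3 libraries, of the Ebf1 level, of dilution by myeloid cells and of feeder RNA, the alternatives of the 2 list differences between the populations, and the overlap of genes lower in both were chosen after their results were seen, as was the choice to count splits for the DESeq2 overlap. The tests of the difference between the populations marked 2 lists. The T lineage list had a more positive E271A effect at day 7 than at day 3 (camera, adjusted p = 5.92e-11, median difference 2.21), and the stromal feeder list a more negative one (camera, adjusted p = 0.00409, median difference -0.78). With an estimated correlation the adjusted p was 0.403 and 0.174. Of 100 splits drawn within both populations, 9 gave a camera p as small as the real 3.7e-12 for the T lineage list (smallest other 4.62e-18), so chance cannot be excluded there. For the stromal list 1 split, the real one, gave a p as small (0.000512, smallest other 0.000624), a share for this list alone that does not allow for its choice among 16 lists. The stromal call was lost without the filter (adjusted p = 0.054) and in 6 of the 12 fits that left out a library. These left out wild-type replicate 1 (0.121) and E271A replicate 3 (0.0891) of day 7 and wild-type replicates 1 (0.0679) and 2 (0.0532) and E271A replicates 1 (0.173) and 3 (0.0694) of day 3. Among feeder genes, Col1a1 held 0 to 20 counts per library. Kit, gate and time differ between the populations as well, and no test here parts them.

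T lineage genes were higher with E271A at day 7. A difference carried by the replicate 3 libraries, which stood apart in Lars2 and Il2ra, was examined by leaving both out. The T score difference was then 1.72, against 1.84 with all libraries, so its size does not rest on them alone. Without them camera gave an adjusted p of 1e-24 in the same direction at the preset correlation, 0.702 with an estimated correlation of 0.59, and fry 0.816. With all libraries these last 2 were 0.678 and 0.77, so they do not decide whether replicate 3 carries the call. Cells with little transgene remain open, although the GFP-positive sort would remove cells without the vector, because the Ebf1 difference of -0.16 has an interval from -0.41 to 0.10. The 10 splits of 6 libraries are too few for a share under 0.05, with a real camera value of 3.1e-13 and a smallest other of 1.3e-24. A biological effect of E271A on the T lineage program is a hypothesis that stays beside these.

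Early B lineage genes were lower with E271A at day 3. Dilution by RNA of additional myeloid cells would lower the markers of other cell types alike. The stem, T lineage and NK members had a mean log2 difference of 0.10 and the early B members of -0.39, a gap of 0.50 (SE 0.10 across genes). The other members were thus not lower on average, as dilution alone would have them. That SE treats genes of the same libraries as independent and does not measure the spread between libraries, so dilution is not decided. A lower transgene level remains open, with Ebf1 higher by 0.12 in E271A and an interval from -0.15 to 0.40. The splits of 6 libraries are too few for a share under 0.05, with a real camera value of 2.55e-13 and a smallest other of 1.53e-10. A weaker action of E271A on early B genes may contribute and is a hypothesis.

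More genes were lower with E271A in both populations than independent lists would give. RNA of feeder cells lost from the E271A libraries is argued against by 3 collagen genes. Col1a1, Col1a2 and Col3a1 together held 0.611 raw CPM in wild type at day 7 and 0.392 at day 3, while the 44 genes lost 11.9 and 8.25 CPM at the median. The argument rests on these 3 of the 22 genes of the stromal feeder list, and the others were not set against the loss. A lower transgene level is not decided by the Ebf1 differences of 0.12 at day 3 and -0.16 at day 7. The splits of both populations were counted for lower and higher genes together, by the larger of the same-way and opposite-way counts. Of their 100 combinations, 15 reached the real 53, the highest other giving 160 and the median 17, so chance cannot be excluded. Genes lower in both were not counted alone over the splits. For the genes that DESeq2 called in both, the same count reached 4 in 1 combination, the real one, and 3 in the highest other. That is a margin of 1 gene in a count chosen after its result was seen, so it does not exclude chance. An effect of E271A common to both populations is a hypothesis only.

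For the other results of models fitted across many genes, the 10 splits of 6 libraries are too few for a share under 0.05. At day 7 edgeR called 0 genes in the real split (695 at an unadjusted p under 0.05) and at most 0 in any other, and DESeq2 79 and at most 260. The real and the smallest other camera p were 0.0402 and 4.56e-15 for the early B list, 0.234 and 2.52e-05 for the Notch list, 1.59e-05 and 2.81e-14 for the NK list, 0.000795 and 5.02e-11 for the erythroid list and 0.000887 and 0.0151 for the p53 list. At day 3 edgeR called 0 (522 at an unadjusted p under 0.05) and at most 10 genes, and DESeq2 32 and at most 177. The camera p were 0.632 and 0.173 for the T list, 0.465 and 0.00248 for the Notch list, 6.08e-14 and 7.25e-15 for the interferon list, 4.12e-05 and 0.000193 for the myeloid list and 0.0069 and 0.00693 for the erythroid list. The number of splits with a result as large, the real one included, was 10 and 4 for the day 7 edgeR and DESeq2 counts and 2, 7, 6, 3, 4 and 1 for the T, early B, Notch, NK, erythroid and p53 lists. At day 3 it was 10 and 4 for the counts and 1, 8, 8, 2, 1 and 1 for the early B, T, Notch, interferon, myeloid and erythroid lists. The splits with 260 and 177 DESeq2 calls set wild-type replicate 1 with E271A replicates 1 and 2 at day 7, and wild-type replicates 1 and 2 with E271A replicate 1 at day 3, and point to a structure of the samples other than the group. All of the 100 splits drawn within both populations gave at least the 0 genes that edgeR called for the difference of the effects, the highest other giving 26.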

How the results depend on the processing

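DESeq2 with the replicate block or with libraries left out, the fits without both replicate 3 (day 7) or both replicate 1 libraries (day 3), the overlap of genes lower in both populations and the alternatives of the list differences between populations were chosen after seeing the data. Of 128 named gene results, 115 kept their sign in all alternatives, and of 32 list results 18 kept their direction. The lists that camera called kept their direction in all alternatives. The fits that left out a library had 2 against 3 libraries, and there the cause of a change was not tested beyond the smaller number of libraries. For the other changes the cause was not tested.

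At day 7 the 0 genes called by edgeR (695 at an unadjusted p under 0.05) became 79 with DESeq2, and remained 0 without each library in turn. The DESeq2 count ran from 37 (without wild-type replicate 1) to 120 (without E271A replicate 1) and was 50 without both replicate 3 libraries. At day 3 the 0 genes called by edgeR (522 at an unadjusted p under 0.05) became 1 with no filter, 32 with DESeq2, 16 without both replicate 1 libraries, and 0 to 4 with a library left out. The DESeq2 count was 51 without both replicate 1 libraries and 15 to 66 with a library left out. For the difference of the effects, the 0 genes of edgeR (464 at an unadjusted p under 0.05) became 7 with DESeq2 and 0 to 3 with a library left out. The correlation of fold changes was 0.046 with DESeq2, over all genes with a count in both populations and not only those that passed the filter. It was 0.0443 to 0.153 with a library left out. Among genes called in at least 1 comparison it has no value, since edgeR called 0. The genes lower in both numbered 27 to 54 with a library left out, and the genes higher in both 4 to 30.

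Every list call of camera was lost with an estimated correlation and in fry. The adjusted p was 0.678 and 0.77 for the T lineage, NK, erythroid and p53 lists at day 7. At day 3 it was 0.304 and 0.283 for the early B and interferon lists, 0.427 and 0.381 for the myeloid list and 0.304 and 0.107 for the erythroid list. For the difference of the effects it was 0.403 and 0.578 for the T lineage list and 0.174 and 0.194 for the stromal list, which was also lost with no filter (0.054) and without both day 7 replicate 3 libraries (0.0684), with 0.002 to 0.173 over the fits with a library left out. The erythroid list lost its call at day 7 without both replicate 3 libraries (0.132) and at day 3 with no filter (0.196). At day 7 the early B (0.0467), cell cycle (0.0457) and nuclear import lists (0.0467) passed with no filter, and the Notch (0.0495), interferon (0.00103), myeloid (0.00404) and interleukin 7 lists (0.0495) without both replicate 3 libraries. At day 3 the cell cycle list passed with RLE (0.0445), the NK list with no filter (0.0484) and without both replicate 1 libraries (0.0108), and the shared lymphoid list without both replicate 1 libraries (0.000394). With a library left out the adjusted p of camera at day 7 ran from 6.24e-23 to 0.000405 for the T lineage list, 5.16e-07 to 0.53 for early B, 0.00852 to 0.98 for Notch, 6.56e-16 to 0.196 for erythroid and 0.000445 to 0.11 for p53. At day 3 it ran from 7.66e-12 to 0.143 for myeloid, 0.00101 to 0.689 for erythroid, 0.0772 to 0.975 for Notch and 0.392 to 0.859 for the T lineage list, and the Notch and T lineage lists turned in direction without E271A replicate 3 (0.742) and 2 (0.859).

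Among lists not called, some passed or turned in direction with a library left out. At day 7 the ranges were 0.00423 to 0.686 for shared lymphoid, 0.00244 to 0.98 for myeloid, 0.135 to 0.98 for dendritic, 9.79e-05 to 0.98 for cell cycle, 0.042 to 0.733 for immediate early, 1.13e-05 to 0.364 for interferon and 0.0284 to 0.949 for interleukin 7. These ranges mix directions. The myeloid list passed upward without E271A replicates 1 (0.00244) and 3 (0.0187) but downward without E271A replicate 2 (0.0461). The immediate early list passed only against its main direction, without E271A replicate 3 (0.042). The nuclear import list passed without wild-type replicate 1 (0.0222) and E271A replicates 2 (0.0461) and 3 (0.0281). At day 3 the ranges were 0.16 to 0.981 for dendritic and 0.135 to 0.986 for interleukin 7. The NK list passed without wild-type replicate 1 (0.00498), shared lymphoid without E271A replicate 1 (0.0037) and cell cycle without wild-type replicate 3 (0.0081) and E271A replicate 2 (0.0126). The dendritic list turned with no filter (0.976 at day 7, 0.818 at day 3) and at day 7 without both replicate 3 libraries (0.96), as did the immediate early list (0.815). At day 3 without both replicate 1 libraries the stromal list (0.8) and the interleukin 7 list (0.772) turned.

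Log2 differences that changed sign belonged to genes that neither edgeR nor DESeq2 called without the block. At day 7 Klf1 was 0.025 with limma-voom and 0.009 without both replicate 3 libraries, and Tnpo3 0.017 without these. With a library left out, Klf1 ran from -0.391 to 0.458, Tnpo3 from -0.057 to 0.011, Cd19 from -0.108 to 0.537, Pax5 from -1.449 to 0.099, Notch1 from -0.068 to 1.547, Trbc2 from -0.669 to 5.583, Cd3d from -0.295 to 6.452 and Thbs1 from -0.364 to 0.04. At day 3 Gata3 (0.002) was -0.005 with RLE, -0.003 with no filter, 0 with the 1 CPM filter, -0.004 with DESeq2, -0.005 with all 12 libraries in 1 fit, and -0.007 without both replicate 1 libraries, where Hes1 was -0.05. With a library left out, Gata3 ran from -0.083 to 0.044, Hes1 from -0.026 to 0.452, Ebf1 from -0.023 to 0.2, Tcf7 from -0.475 to 0.016 and Notch1 from -0.225 to 0.04.

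The labels do not say that the replicate numbers pair the samples. Same-numbered libraries deviated together with r of 0.132, 0.0141 and 0.422 at day 7 and 0.224, 0.0829 and 0.191 at day 3, and so were not treated as pairs. At day 3 every library correlated best with its own number, a hint from the data, but at day 7 wild-type replicate 2 correlated best with E271A replicate 1 (0.12) and E271A replicate 2 with wild-type replicate 1 (0.122). With the replicate block, edgeR called 3 genes at day 7, 0 at day 3 and 2 for the difference of the effects, and DESeq2 called 169 at day 7 and 48 at day 3. Tcrg-C1 was among the edgeR calls at day 7 with the block, and at an unadjusted p under 0.05 there were 66 genes lower and 32 higher in both populations. With the block the early B and Notch (adjusted p = 0.0206 each), shared lymphoid (0.00297) and cell cycle lists (0.048) passed at day 7, and the shared lymphoid list at day 3 (0.0458). Gata3 at day 3 was -0.001.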

Other observations

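Genes in this part were chosen after their values were seen. Prg2, which encodes eosinophil major basic protein (chromosome 2, 84980461 to 84983632), was at 412 ± 44.7 CPM with wild type and 911 ± 476 CPM with E271A at day 7, and at 464 ± 29.3 and 722 ± 121 CPM at day 3, where DESeq2 called it (adjusted p = 0.000544, against 0.505 at day 7). In both populations every E271A library lay above every wild-type library. Prg3, its homologue, was at 34.3 ± 8.21 and 63.9 ± 29.8 CPM at day 7 and at 22.2 ± 3.05 and 29.8 ± 4.59 CPM at day 3, not called by DESeq2 or edgeR. Mafb, a monocyte and macrophage factor and a member of the myeloid list, was lower in every E271A library of both populations (7.52 ± 2.05 against 3.88 ± 1.13 CPM and 1.09 ± 0.301 against 0.559 ± 0.157 CPM), also without a call.

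The next 5 genes are among the 63 that DESeq2 called lower at day 7 and edgeR did not, and no group of genes was tested here. S1pr3, a receptor of sphingosine 1-phosphate, was at 68.7 ± 12.3 CPM with wild type and 31.9 ± 6.57 CPM with E271A. Vegfa, the vascular endothelial growth factor, was at 139 ± 13.1 and 87.8 ± 1.76 CPM. Egfl7 was at 30.3 ± 5.22 and 17.0 ± 1.36 CPM, and Robo4 at 3.05 ± 1.81 and 0.485 ± 0.128 CPM. Trib3, a pseudokinase gene induced by stress, was at 40.6 ± 18.3 and 15.2 ± 2.56 CPM. Skap1, an adaptor of T cells outside the fixed T list, was higher, at 0.734 ± 0.280 and 4.82 ± 3.72 CPM (DESeq2 adjusted p = 0.00903). At day 3 Sell, which encodes L-selectin, was at 108 ± 6.29 CPM with wild type and 71.5 ± 5.18 CPM with E271A (DESeq2 adjusted p = 3.76e-06).

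DESeq2 also called Themis, a T cell gene, and Klhl13 at day 7, both below the filter used for edgeR. Themis held 0, 0 and 6 counts in the wild-type libraries and 22, 10 and 118 in the E271A libraries. Klhl13 held 43, 11 and 10 counts with wild type and 0 in each E271A library. The mast cell protease gene Tpsb2 held 0 counts in both replicate 3 libraries at day 7 and 113, 584, 82 and 1332 counts in the others.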
